A study of Homo sapiens with 40 samples.

How the data were processed

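Per the file headers, the deposited values are raw counts of fragments per gene, made by the authors with featureCounts 1.4.4 as reverse-stranded pairs over GENCODE 19 exons restricted to Agilent version 4 exome targets. Alignment with STAR to GRCh37 is stated in the submitters' processing notes. Libraries were stranded by uridine digestion, made from 1 to 3 µg of total RNA and sequenced on an Illumina HiSeq. Poly(A) libraries were selected on oligo(dT) beads, and the others by hybridisation to exome probes. Every one of the 40 libraries and 24675 genes was used as given. Gene length means the targeted length in the files, and positions are GRCh37 positions of the targeted exons from the files. Symbols, synonyms, gene types and transcript sequences came from GENCODE 29 and RefSeq by gene identifier alone, and 23807 of the identifiers were matched. The dose of MDV3100 and the meaning of the numbers 1 to 8 in the titles are not given in the sources used here. One DHT pair carries RIN 2 in capture and RIN 2.5 in poly(A) and was taken as 1 RNA by its replicate number.

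Depth is in M (mega, 10 to the power 6) assigned fragments per library. Intact libraries held 17.1, 20 and 15.4 (DHT poly(A)), 15.5, 19.5 and 16.4 (MDV poly(A)), 27.5, 25.3 and 25.0 (DHT capture) and 29.2, 27.2 and 21.4 (MDV capture). At RIN 5.7, 7.3, 8.2 or 8.3, and 9.1 or 9 they held 6.30, 6.86, 7.37 and 11.7 (DHT poly(A)), 5.32, 4.80, 7.02 and 9.55 (MDV poly(A)), 26.5, 29.3, 26.5 and 23.7 (DHT capture) and 24.9, 28.6, 28.6 and 30.7 (MDV capture). At low RIN they held 9.80 (RIN 2.4), 8.90 (2.5) and 7.52 (3.5) for DHT poly(A), 7.84 (3.3), 7.64 (3) and 7.17 (3.6) for MDV poly(A), 31.3 (2.4), 27.7 (2) and 28.7 (3.5) for DHT capture and 28.9 (3.3), 27.3 (3) and 28.4 (3.6) for MDV capture. Between technical replicates, the chi-square of counts per degree of freedom was 1.72 to 10.0, above the 1 of pure counting error.

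The 14 comparisons, their tests, the gene lists and 87 alternatives were fixed before the data were examined, and 10 alternatives were added afterwards. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F tests). Adjustment was by Benjamini and Hochberg at 0.05 within each comparison. Treatment was compared within each protocol for intact and for low RIN RNA. Protocol and RIN contrasts carried treatment in the model, and differences of effects were interaction terms. RIN trends used RIN as a number over the 20 libraries of a protocol, with treatment in the model. SE is the log2 fold change divided by the square root of F. A gene with no fragment in a group is given as at least a fold, against 3 fragments over that group. Such bounds and SEs cover the spread of libraries or counting only. Placing all-zero members at their bounds left the list median unchanged in all 9 cases of a list and comparison that hold one.

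Named genes are those with the largest changes in each direction (at most 10, adjusted p under 0.05, a mean of at least 5 CPM in the higher group, a symbol, and no overlap between groups within each treatment), up to 2 called members in each direction of a described list, and KLK3, KLK2, TMPRSS2, FKBP5, ERG, ACTB and GAPDH in any comparison. A few further genes are not reported here. From these the text gives 20 to 30 per comparison at most. The 23 lists cover androgen-induced and androgen-repressed genes, sterol and fatty acid synthesis, endoplasmic reticulum stress and secretion, S phase, mitosis, polyamine synthesis, steroid metabolism, and neuroendocrine, luminal, basal and stromal, endothelial and leukocyte markers. They also cover immediate-early and heat shock genes, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, ribosomal proteins, nuclear and prostate long noncoding RNAs, very long and very short coding mRNAs, histones, zinc finger genes, and small nucleolar and Cajal body RNAs. List names are labels only. Where members of the nuclear long noncoding list, such as DANCR and SNHG5, lie in the cell was not examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated per list, adjusted over the lists of a comparison. Lists with fewer than 3 tested genes were not tested. Members were also adjusted over their list alone.

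Similarity is the Pearson correlation, across genes, of log2 CPM (prior count 2) with the mean of the intact libraries of the same treatment and protocol, each intact library against the others. Its relation to RIN over 7 libraries was tested by exact permutation of 5040 orders, and capture against poly(A) by exact sign changes (128) over 7 pairs. Length was examined in 10 bins of targeted length. Alternatives were DESeq2 1.42.0, relative log expression factors, no filter, omission of each library, thinning to the lowest total of a set (7.17 M), 1 fit over both protocols, RIN as a covariate, another reference RIN, a replicate block, the title number as a factor, ranks of RIN, other gene filters, prior counts and bins. Labels of groups were exchanged in all 10 ways for 3 against 3 libraries and in 100 random ways otherwise.

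The tests were tested on simulated data with 200 genes changed by 1.5-, 2- or 4-fold (67, 67 and 66 genes). For DHT against MDV in intact RNA, 85.1%, 95.5% and 98.5% were recovered in poly(A) and 85.1%, 94.0% and 98.5% in capture. At low RIN the shares were 7.46%, 37.3% and 77.3% in poly(A) and 4.48%, 23.9% and 92.4% in capture. Degradation gave 28.4%, 55.2% and 87.9% in poly(A) and 41.8%, 94.0% and 100% in capture. Protocol gave 83.6%, 97.0% and 98.5% in intact RNA and 8.96%, 53.7% and 89.4% at low RIN. Interactions gave 76.1%, 88.1% and 95.5% for the DHT effect by protocol, 8.96%, 50.8% and 81.8% for degradation by protocol, 4.48%, 20.9% and 65.2% for the DHT effect by RIN in poly(A) and 0%, 28.4% and 90.9% in capture. RIN trends gave 1.49%, 41.8% and 84.8% in poly(A) and 32.8%, 80.6% and 95.5% in capture. False calls were at most 13 of 13808 unchanged genes in any comparison. Simulated genes were independent, with 1 mean per gene, a spread set by mean count alone and no effect beyond the planted folds. Correlated genes and differences in RIN within a group were not simulated, so these shares are not error rates of the real comparisons. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.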

Results

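RNA of the VCaP prostate cancer cell line was sequenced from poly(A)-selected and from exome-capture libraries, with intact RNA and with RNA degraded under control. VCaP cells carry a fusion that puts ERG under the androgen-driven promoter of TMPRSS2. Cells spent 24 h in androgen-depleted medium. They then received 1 nM dihydrotestosterone (DHT), an androgen, or MDV3100 (MDV, enzalutamide), an antiandrogen, for 24 h. Lysate kept at 37 °C gave RNA of falling RNA integrity number (RIN). The 40 libraries cover 2 treatments and both protocols. Each combination holds 3 intact libraries (RIN 10), 4 libraries from RIN 9.1 or 9 to 5.7, and 3 low RIN libraries (RIN under 4). The intact libraries are technical triplicates, so p-values measure the spread of libraries and not of cultures. The low RIN libraries differ in RIN within a group (DHT 3.5, 2.4 and 2 or 2.5, MDV 3.6, 3.3 and 3) and are not strict replicates.

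Counts cover 24675 genes, of which 18643 are protein-coding. Capture libraries hold 21.4 to 31.3 M assigned fragments. Intact poly(A) libraries hold 15.4 to 20 M, low RIN ones 7.17 to 9.80 M, and those between 4.80 to 11.7 M. A fragment was seen for 12472 to 16477 genes per poly(A) library and 16290 to 20308 per capture library. The 100 most abundant genes took 21.2 to 24.8% of the fragments in intact poly(A) libraries, up to 56.3% at low RIN, and 14.6 to 24.2% in capture. Ribosomal protein genes took 8.62 to 8.72% of the intact DHT and 13.4 to 14.3% of the intact MDV poly(A) libraries. Their share was 22.8 to 30.7% and 35.5 to 44.2% in the low RIN poly(A) libraries of DHT and MDV, against 0.581 to 1.54% in capture.

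How far did each degraded library move from intact RNA of its own treatment and protocol? In capture, the correlation of log2 counts with the intact mean fell with RIN from 0.993 at RIN 9.1 to 0.969 at RIN 2.4 in DHT. Across the 7 degraded libraries it followed RIN with r = 0.966 in DHT (rho = 0.964, exact p = 7.9e-04, adjusted p = 0.0032) and r = 0.961 in MDV (rho = 0.893, exact p = 0.0028, adjusted p = 0.0056). These relations belong to a family of 4. Without the 2 farthest libraries r was 0.962 in DHT and 0.934 in MDV. Poly(A) libraries gave r = 0.310 (rho = 0.286, exact p = 0.47, adjusted p = 0.47) in DHT and r = 0.418 (rho = 0.464, exact p = 0.33, adjusted p = 0.44) in MDV, and 0.319 and 0.498 without the 2 farthest. The poly(A) library at RIN 9.1 was less similar to intact RNA (0.950) than that at RIN 7.3 (0.960) in DHT, and RIN 9 (0.938) less than RIN 7.3 (0.965) in MDV. Capture lay nearer to intact RNA than poly(A) in 7 of 7 pairs of each treatment, by 0.0278 ± 0.0107 (SD) in DHT and 0.0346 ± 0.0152 in MDV. Their exact sign-change p of 0.016 is the smallest possible with 7 pairs. Degraded capture libraries were deeper than degraded poly(A) ones. Similarity also ran over 21528 (DHT) and 21021 (MDV) genes in capture against 17686 and 18305 in poly(A). Neither depth nor gene set was made equal for this comparison. Over genes of at least 10 CPM alone, the mean difference was larger (0.0540 in DHT and 0.0579 in MDV) but kept no call (exact adjusted p = 0.14 and 0.13), and the poly(A) relation to RIN turned to r = -0.349 and -0.0276. Numbers in the titles separate RIN 8.2 and above from RIN 7.3 and below, so 5 libraries at most carry one number and no relation within a number was tested.

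**Figure D1:**
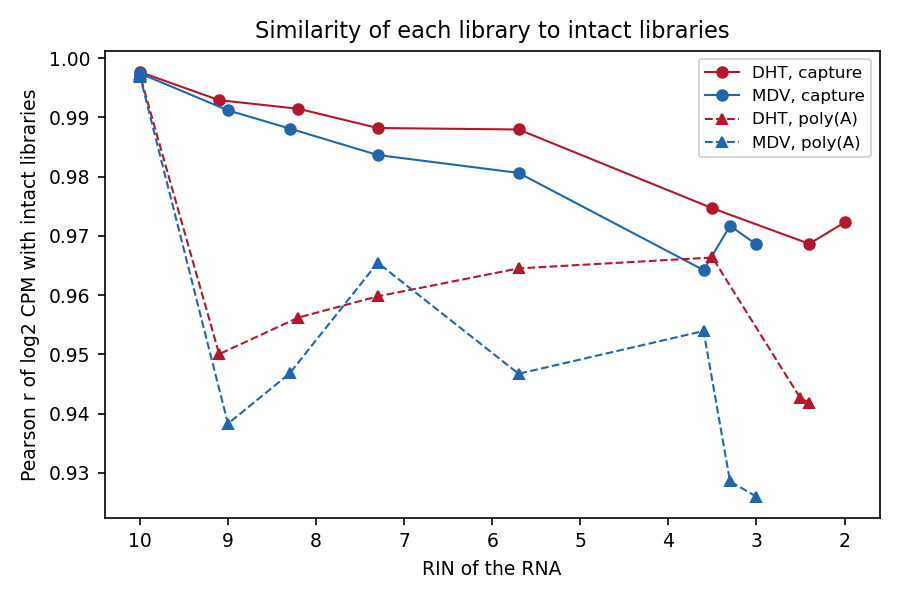
Correlation of each degraded library with the mean of the intact libraries of the same treatment and protocol, against RIN.

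Which genes answered to the androgen in intact poly(A) libraries? With DHT against MDV (3 libraries each), 5206 of 13333 genes were higher and 5385 lower, 1406 and 1973 of them at least 2-fold. KLK3, which encodes prostate-specific antigen, rose with DHT from 16.2 to 583 CPM (log2 fold change 5.30 ± 0.05 SE, edgeR adjusted p = 4.3e-20, 19:51358171-51363474, whose reads can be shared with its near copy KLK2 at 1.29 ± 0.05). The glucocorticoid receptor chaperone FKBP5 rose by 4.22 ± 0.05, the protease TMPRSS2 by 3.92 ± 0.04 and the fused oncogene ERG by 2.93 ± 0.05. Reference genes moved too, ACTB by 0.39 ± 0.04 and GAPDH by 0.36 ± 0.05. The metalloreductase STEAP4 (181 against 2.21 CPM) rose by 6.48 ± 0.08, the matrix protein gene SPARC by 6.79 ± 0.29 and the glucose transporter gene SLC2A3 by 5.49 ± 0.28. PGC, which encodes pepsinogen C, had no fragment in MDV and was at least 358-fold higher with DHT, against a floor of 3 fragments over the group. Of genes lower with DHT, CCN3 (-7.47 ± 0.11), REG4 (-6.85 ± 0.18), the ligand genes WNT2 (-6.18 ± 0.11) and SHH (-5.80 ± 0.08) and the chromatin organiser SATB1 (-5.89 ± 0.13) moved most. The androgen-inactivating enzymes UGT2B17 (-5.95 ± 0.27) and UGT2B15 (-5.79 ± 0.13), near copies that share reads, were lower as well.

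Gene lists place these genes in programmes. Androgen-induced genes were higher for 38 and lower for 2 of 40 (median 1.83, camera adjusted p = 8.1e-56), the exceptions being ADAM7 (-3.59 ± 0.18) and PTGER4 (-3.09 ± 0.13). Androgen-repressed genes were lower for 15 and higher for 4 of 19 (median -2.18, adjusted p = 3.4e-10). All 30 sterol and fatty acid synthesis genes were higher (median 1.42, adjusted p = 1.3e-27), with the lipid transfer gene STARD4 at 3.45 ± 0.13 and the sterol sensor INSIG1 at 2.42 ± 0.04. Endoplasmic reticulum stress and secretory genes were higher for 23 of 24 (median 1.66, adjusted p = 2.4e-27), led by the retrieval receptor KDELR3 (4.30 ± 0.16) and SDF2L1 (3.33 ± 0.09), while ATF4 was lower (-0.53 ± 0.05). All 30 mitosis genes were lower with DHT (median -2.0, adjusted p = 9.7e-35), among them CDC25C (-3.17 ± 0.10) and TOP2A (-3.05 ± 0.05). S phase genes split, 17 higher and 9 lower of 30 (median 0.38, adjusted p = 0.28), with CDC6 at 1.57 ± 0.07 and TYMS at -0.80 ± 0.08. Polyamine synthesis genes were higher for 6 and lower for 1 of 11 (median 0.61, adjusted p = 7.8e-03, 0.11 with an estimated correlation), ODC1 at 2.03 ± 0.04. Steroid metabolism genes were higher for 4 and lower for 7 of 12 (adjusted p = 0.59).

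Of markers of cell type in the same comparison, neuroendocrine genes were lower for 9 and higher for 3 of 13 (median -0.90, adjusted p = 0.016, 0.23 with an estimated correlation), with the adhesion gene NCAM1 at -4.43 ± 0.18 and DDC at -3.59 ± 0.13. Luminal genes were higher for 11 and lower for 4 of 16 (median 0.26, adjusted p = 0.044, 0.19 with an estimated correlation), the keratin KRT8 at 1.67 ± 0.04. Basal genes were higher for 3 and lower for 2 of 5 (adjusted p = 0.49), the keratin KRT14 at 4.77 ± 0.19. Stromal, endothelial and leukocyte genes were higher for 2 and lower for 5 of 7 (adjusted p = 0.18). Immediate-early and heat shock genes were higher for 16 and lower for 8 of 24 (adjusted p = 0.55). Nuclear genes of oxidative phosphorylation were higher for 63 and lower for 3 of 72 (median 0.55, adjusted p = 3.3e-06, 0.099 with an estimated correlation). Ribosomal protein genes, whose reads are shared with processed copies, were lower for 74 and higher for 1 of 78 (median -0.43, adjusted p = 3.5e-07, 0.19 with an estimated correlation). Nuclear long noncoding RNAs were lower for 7 and higher for 1 of 8 (adjusted p = 0.012, 0.13 with an estimated correlation). Very long coding mRNAs were lower for 24 and higher for 13 of 39 (median -0.27, adjusted p = 3.4e-03), very short ones higher for 20 and lower for 9 of 32 (median 0.57, adjusted p = 7.8e-03). Both calls were lost with an estimated correlation (adjusted p = 0.31 each). Histone genes (8 higher and 5 lower of 18, adjusted p = 0.80), zinc finger genes (108 and 230 of 463, adjusted p = 0.086) and small nucleolar and Cajal body RNAs (6 and 2 of 27, adjusted p = 0.95) gave no list call. Adjusting over the list alone changed the counts of S phase genes (17 higher and 10 lower), very short mRNAs (21 and 9), zinc finger genes (105 and 228) and small nucleolar RNAs (4 and 1). Mitochondrially encoded genes are absent from the counted features (0 of 13), and of 16 prostate long noncoding RNAs 3 are present, too few to test. One of them, PCAT7, was lower with DHT (-0.68 ± 0.14).

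Capture libraries of the same intact RNA gave a similar picture, with the differences given in the next paragraph. There 5612 of 14195 genes were higher and 5776 lower with DHT (3 libraries each), 1377 and 2109 of them at least 2-fold. KLK3 rose by 5.05 ± 0.06, FKBP5 by 3.72 ± 0.05, TMPRSS2 by 3.36 ± 0.04, ERG by 2.56 ± 0.04 and KLK2 by 0.92 ± 0.04. SPARC (6.44 ± 0.25), the RNA-binding protein gene RBM24 (6.37 ± 0.17), STEAP4 (6.20 ± 0.07), SLC2A3 (6.18 ± 0.24) and the T-box factor gene TBX15 (5.46 ± 0.20) led the rise. REG4 (-6.87 ± 0.14), CCN3 (-6.72 ± 0.10), WNT2 (-6.18 ± 0.09), the channel gene TRPM3 (-6.14 ± 0.27) and SHH (-5.57 ± 0.08) led the fall. Androgen-induced genes were higher for 37 of 40 (median 1.71), sterol genes for 30 of 30 (median 1.33) and secretory genes for 23 of 24 (median 1.45), and 30 of 30 mitosis genes were lower (median -1.96). These 4 lists keep their camera call with an estimated correlation. The androgen-repressed list was lower for 15 of 19 (adjusted p = 2.8e-10, 0.070 with an estimated correlation). Immediate-early genes had a median of 0.09 but a mean of -0.27 (12 higher and 9 lower of 25, adjusted p = 0.68). FOSB (-3.35 ± 0.17) and FOS (-2.39 ± 0.10) were far lower with DHT. Over 13251 genes the log2 fold changes of both protocols correlated with r = 0.97, where genes are not independent replicates. Of genes called in both, 4885 were higher and 4870 lower with DHT in both protocols and 24 moved in opposite directions.

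Where did the DHT effect differ between protocols? With 12 intact libraries, the log2 fold change was more positive in capture for 75 of 14202 genes and more negative for 291, 5 and 43 of them by at least 2-fold. That split depends on scaling, since relative log expression factors gave 108 of 324 in the positive direction. The count also depends on single libraries, at 219 without intact MDV capture replicate 1, 240 without intact DHT capture replicate 1 and 778 without intact DHT capture replicate 3. Single genes with very negative differences include several of the immediate early response. The signalling regulator RGS2 (-2.74 ± 0.42), IER5 (-2.68 ± 0.47) and FOSB (-2.08 ± 0.51) were lower with DHT in both protocols, and more so in capture, RGS2 at -3.62 ± 0.16 against -0.93 ± 0.34 in poly(A). The apoptosis gene PMAIP1 (-3.74 ± 0.31, adjusted p = 1.4e-08), the kinase SGK1 (-2.62 ± 0.20) and the synaptic gene ARC (-2.5 ± 0.21) were lower with DHT in capture but higher in poly(A), PMAIP1 at -2.92 ± 0.15 against 0.76 ± 0.27. All of these genes had few fragments in intact poly(A) libraries, at most 109 (SGK1). PMAIP1 had 11 to 17 per MDV and 16 to 26 per DHT library, RGS2 14 to 27 and 6 to 12. Their directions in poly(A) rest on these low counts. SCARNA13 (1.28 ± 0.23), the growth arrest RNA GAS5 (0.81 ± 0.06) and HNRNPA1 (0.68 ± 0.08) fell less with DHT in capture. TMPRSS2 (-0.62 ± 0.06), FKBP5 (-0.56 ± 0.07), ERG (-0.43 ± 0.06), KLK2 (-0.43 ± 0.06) and KLK3 (-0.32 ± 0.08) rose less in capture. All 9 lists that follow hold with an estimated correlation. The DHT effect on androgen-induced genes was more negative in capture for 17 and more positive for 0 of 40 (24 and 1 over the list alone, median -0.26). Sterol (6 of 30, 7 over the list alone, median -0.09), secretory (8 of 24, 15 over the list alone, median -0.17) and polyamine genes (3 of 11, 5 over the list alone, median -0.09) had the same sign. It was more negative for 5 and more positive for 1 of 25 immediate-early genes (12 and 1 over the list alone, median -0.21), for 7 and 0 of 72 oxidative phosphorylation genes (15 and 2, median -0.11) and for 7 and 1 of 24 histone genes (10 and 2, median -0.53). Ribosomal protein genes, with a median DHT effect of -0.43 in poly(A) and -0.23 in capture, were more positive in capture for 17 of 78 (38 over the list alone, median 0.20). Nuclear long noncoding RNAs, at -0.67 and -0.32, were more positive for 3 and more negative for 1 of 8 (4 and 1, median 0.36). With relative log expression factors the sterol and polyamine medians shrink to -0.056 and -0.053, and without a filter that of nuclear long noncoding RNAs shrinks to 0.088. The luminal median flips sign with the scaling and the basal one without a filter, so neither gives a direction here, and the basal median lies opposite to its test.

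**Figure D2:**
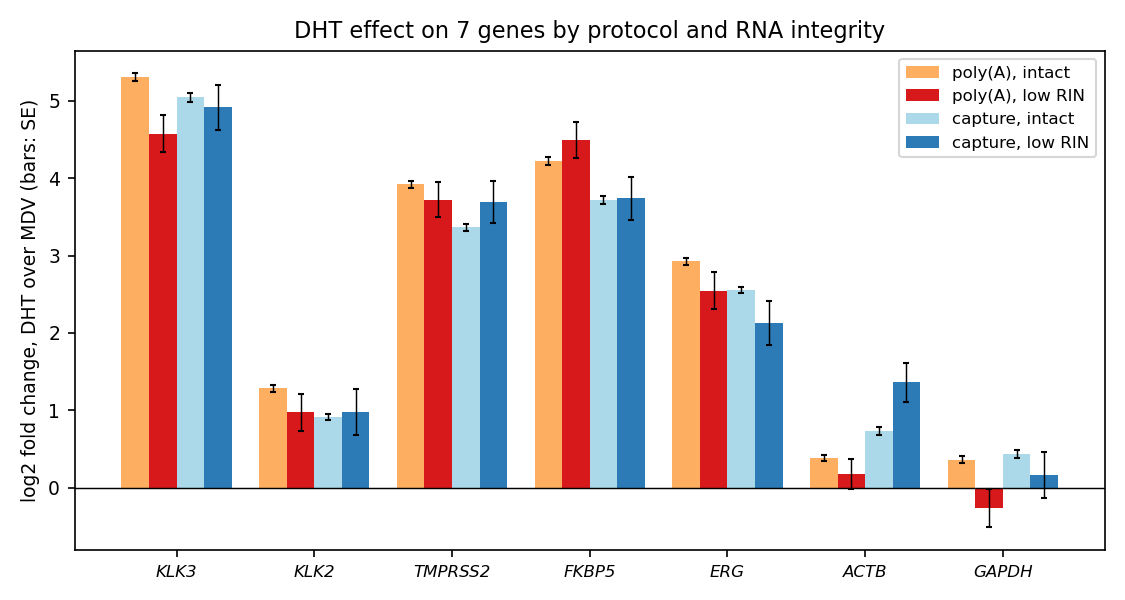
log2 fold change of the fixed androgen genes, DHT against MDV, in intact and low RIN libraries of both protocols.

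What did capture and poly(A) see differently in intact RNA? Over 12 libraries, 5684 of 14202 genes were higher and 5133 lower in capture, 716 and 1102 of them at least 2-fold. RNAs without a poly(A) tail led the rise: the Cajal body RNAs SCARNA10 (9.08 ± 0.12) and SCARNA7 (7.29 ± 0.12), telomerase RNA TERC (5.66 ± 0.14), and the histone genes H4C3 (7.20 ± 0.09) and H1-4 (7.15 ± 0.14), families whose members share reads. The nuclear RNA NEAT1 was higher by 4.62 ± 0.12 and FOS by 2.92 ± 0.14. Lower in capture were RPS7 (-6.31 ± 0.06), RPL22 (-6.15 ± 0.07), RPS27 (-5.64 ± 0.09), the respiratory subunit NDUFB3 (-5.60 ± 0.16), the actin nucleator ARPC3 (-5.53 ± 0.05), the spermine synthase gene SMS (-5.02 ± 0.06) and the chaperone gene HSPD1 (-4.69 ± 0.04). GAPDH was lower by 3.47 ± 0.05, ACTB by 1.55 ± 0.05, KLK3 by 0.68 ± 0.05, KLK2 by 0.62 ± 0.06, FKBP5 by 0.39 ± 0.07, TMPRSS2 by 0.36 ± 0.07 and ERG by 0.34 ± 0.06. Ribosomal protein genes were lower for 77 of 78 (median -3.52), histone genes higher for 23 of 24 (median 3.06), small nucleolar and Cajal body RNAs higher for 64 and lower for 3 of 74 (65 and 4 over the list alone, median 1.99), very long mRNAs higher for 39 of 39 (median 0.75, with the centrosomal gene ALMS1 at 1.67 ± 0.04) and oxidative phosphorylation genes lower for 60 and higher for 9 of 72 (median -0.78). These 5 lists hold with an estimated correlation. The call of very short mRNAs (27 lower and 4 higher of 32, median -1.15, adjusted p = 9.2e-10) does not (adjusted p = 0.068). In nuclear long noncoding RNAs the median (-1.34) and mean (0.10) differ in sign, and so do those of immediate-early genes (0.24 and -0.12). Protocols also differ in how each gene is targeted and selected, so these folds are not differences in abundance.

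Which genes changed with degradation in poly(A) libraries? Between 6 low RIN and 6 intact libraries, 3431 of 13310 genes were higher and 3678 lower, 1650 and 1695 of them at least 2-fold. Among the largest rises were ANKRD18B (8.25 ± 0.60), CCDC34 (5.38 ± 0.36), PHF14 (5.29 ± 0.39), the U1 splicing factor gene LUC7L3 (5.21 ± 0.17, adjusted p = 5.2e-12, 17:48796955-48829748), SREK1IP1 (5.19 ± 0.44), the initiation factor gene EIF5B (5.13 ± 0.34) and the decay factor gene UPF2 (4.91 ± 0.24). ANKRD18B, CCDC34, SREK1IP1 and EIF5B carry A-rich coding stretches that can be caught by poly(A) selection. Falls were led by RNF207 (-4.09 ± 0.59), the prolactin receptor gene PRLR (-4.04 ± 0.56), the repressor ZBTB20 (-3.97 ± 0.54), APC2 (-3.43 ± 0.48) and the chloride transporter gene SLC12A2 (-2.78 ± 0.25). TMPRSS2 fell by 0.48 ± 0.09, ERG by 0.31 ± 0.13 and FKBP5 by 0.28 ± 0.11. GAPDH (1.25 ± 0.14) rose, and so did KLK3 (0.43 ± 0.13) and KLK2 (0.37 ± 0.11) after TMM scaling. In CPM without TMM factors both KLK genes were lower at low RIN, so their direction depends on scaling. KLK3 was at 404 to 435 CPM against 573 to 591 in intact DHT libraries, and 11.8 to 15.6 against 15.8 to 16.7 in MDV. KLK2 was at 7050 to 7654 against 9583 to 9606 in DHT, and 2686 to 3388 against 3948 to 4505 in MDV. Ribosomal protein genes were higher for 77 of 78 (median 2.21, adjusted p = 4.0e-62), with RPS29 at 3.43 ± 0.32 and RPL35 at 3.37 ± 0.18. Sterol genes were lower for 20 and higher for 5 of 30 (21 and 5 over the list alone, median -0.66, adjusted p = 3.0e-05), SCD at -2.06 ± 0.11. The list labelled nuclear long noncoding RNAs was higher for 5 and lower for 1 of 8 (6 and 1 over the list alone, median 1.25, adjusted p = 1.9e-03). DANCR was at 3.52 ± 0.19 and SNHG5 at 2.56 ± 0.18, but the nuclear RNA MALAT1 was at -1.84 ± 0.22. These 3 lists hold with an estimated correlation. Androgen-induced genes were lower for 20 and higher for 11 of 40 (median -0.30, adjusted p = 0.015, 0.10 with an estimated correlation). Very short mRNAs were higher for 30 of 32 (median 1.83, adjusted p = 0.084 with an estimated correlation), SEC61G at 3.90 ± 0.26. Oxidative phosphorylation genes were higher for 65 and lower for 2 of 72 (68 and 2 over the list alone, median 1.4, 0.10 with an estimated correlation), NDUFB1 at 2.95 ± 0.22. Very long mRNAs were lower for 27 and higher for 1 of 38 (median -1.08, 0.17 with an estimated correlation), the lipid transfer gene VPS13C at -2.33 ± 0.14 and the methyltransferase gene KMT2A at -2.15 ± 0.21. RIN and the title number change together here. Against RIN 7.3 and 5.7, which carry the number of the low RIN libraries but give fewer libraries and a smaller step, 797 genes were higher and 689 lower. There TMPRSS2 changes sign and is not called, nor are the genes that led the falls (RNF207, PRLR, ZBTB20, APC2 and SLC12A2), SREK1IP1, ERG, FKBP5, KLK2, GAPDH, SCD, VPS13C and KMT2A.

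What did degradation change in capture libraries? There 5268 of 14662 genes were higher and 5384 lower at low RIN (6 against 6 libraries), 2675 and 2360 of them at least 2-fold. The hair protein gene TCHH (4.98 ± 0.55), the muscle genes MYH3 (4.13 ± 0.18) and NEB (3.83 ± 0.20), CEP295NL (4.01 ± 0.18), the kinase partner JAKMIP3 (3.95 ± 0.18) and the protease inhibitor gene SPINK5 (3.79 ± 0.21) rose most. FPGT (-2.91 ± 0.24), CLDND1 (-2.88 ± 0.31), the sugar transporter gene SLC35A5 (-2.81 ± 0.25), ARL6IP1 (-2.75 ± 0.19), BBS10 (-2.71 ± 0.22) and the ATP synthase subunit ATP5MC1 (-2.71 ± 0.22) fell most. ERG (1.06 ± 0.13) and FKBP5 (0.46 ± 0.10) were higher, and KLK3 (-0.59 ± 0.11) and ACTB (-0.62 ± 0.13) lower. Very long mRNAs were higher for 34 and lower for 2 of 39 (median 1.5, adjusted p = 2.3e-15), with the chromatin regulator ANKRD11 at 3.4 ± 0.24. Sterol genes were lower for 22 and higher for 3 of 30 (median -1.03, adjusted p = 4.7e-06), SC5D at -2.55 ± 0.23, and oxidative phosphorylation genes lower for 55 and higher for 7 of 74 (56 and 7 over the list alone, median -0.73, adjusted p = 4.7e-06). Small nucleolar and Cajal body RNAs were lower for 56 and higher for 8 of 78 (median -1.35, adjusted p = 2.5e-04). RIN and the title number change together here too, and against RIN 7.3 and 5.7 only 1485 genes were higher and 1311 lower, without ERG, FKBP5, KLK3 and ACTB. No list held with an estimated correlation, which gave an adjusted p of 0.34 for the very long mRNA and sterol lists, 0.56 for oxidative phosphorylation and 0.66 for the small RNAs. At DHT RIN 2 and MDV RIN 3.6 the capture libraries hold reads of silent genes, so folds of rare genes here include reads that need not be RNA.

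Change followed gene length in opposite directions. In poly(A), the tenth of genes with the shortest target (up to 630 bases, 1331 genes) had a median log2 fold change of 0.84 and the tenth with the longest (from 3841 bases) one of -0.85. The difference of -1.69 had an SD of 0.29 over the 6 low RIN libraries. In capture the difference was 1.46 (SD 0.21). Rank correlations of fold with target length were -0.493 over 13310 genes in poly(A) and 0.422 over 14662 in capture, and genes are not independent replicates. Between the protocols, folds of low RIN against intact RNA correlated with r = -0.14, and 3479 genes called in both moved in opposite directions against 773 higher and 1148 lower in both.

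**Figure D3:**
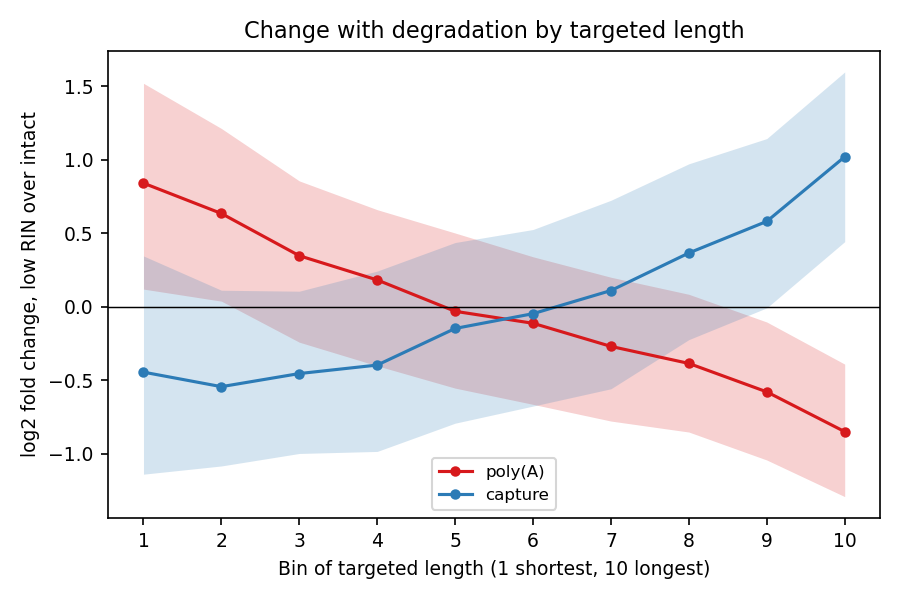
Median log2 fold change of low RIN against intact libraries in 10 bins of targeted gene length, poly(A) and capture.

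Which changes with degradation differed between protocols? With 24 libraries, 5316 of 14653 genes had a more positive and 4119 a more negative change in capture, 4269 and 2982 of them at least 2-fold, around an all-gene median of 0.24. ANKRD11 (4.41 ± 0.29), NEB (4.39 ± 0.46) and the proliferation gene MKI67 (4.10 ± 0.19) moved up. SREK1IP1 (-5.75 ± 0.47), the translocon subunit SEC61G (-3.95 ± 0.43) and RPL22 (-3.74 ± 0.27) moved down. ERG (1.59 ± 0.21), FKBP5 (0.90 ± 0.19) and TMPRSS2 (0.61 ± 0.16) were more positive, KLK3 (-0.84 ± 0.18) and GAPDH (-1.35 ± 0.23) more negative. Very long mRNAs were higher for 37 of 40 (median 2.63) and polyamine genes lower for 9 of 11 (median -0.87), ODC antizyme gene OAZ2 at -2.30 ± 0.16, and both hold with an estimated correlation. Ribosomal protein genes were lower for 78 of 78 (median -2.12, 0.17 with an estimated correlation), oxidative phosphorylation genes for 70 of 72 (median -1.97, 0.16) and very short mRNAs for 30 of 32 (median -2.14, 0.20).

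At low RIN, what separated capture from poly(A)? Over 12 libraries 5302 of 13989 genes were higher and 4394 lower in capture, 4492 and 3541 at least 2-fold, around an all-gene median of 0.22. CEP295NL (at least 220-fold), the phosphatase gene PPM1L (at least 196-fold) and SCARNA5 (at least 168-fold) had no fragment in low RIN poly(A) libraries. The protocadherins PCDHGB7 (at least 193-fold) and PCDHGA11 (at least 162-fold) share their last exons. MALAT1 (4.58 ± 0.43), NEAT1 (4.99 ± 0.41), NEB (5.41 ± 0.49) and MKI67 (5.56 ± 0.23) were higher as well. SNHG19 (-10.03 ± 0.50), RPL22 (-9.93 ± 0.36), RPS7 (-9.76 ± 0.33), GCSH (-9.41 ± 0.39), NDUFB3 (-8.76 ± 0.37) and SNHG5 (-8.44 ± 0.28) were lowest. ERG (1.17 ± 0.20) and FKBP5 (0.53 ± 0.18) were higher in capture, KLK3 (-1.53 ± 0.17), KLK2 (-0.91 ± 0.20), ACTB (-1.86 ± 0.22) and GAPDH (-4.86 ± 0.26) lower. Ribosomal protein genes were lower for 78 of 78 (median -5.83) and very long mRNAs higher for 39 of 40 (median 3.23), each with an adjusted p of 0.076 with an estimated correlation, and no list held with it. Of 1677 genes at least 2-fold apart in intact RNA and also tested at low RIN, 85.6% were called in the same direction here.

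Did the answer to DHT survive in low RIN poly(A) libraries? Of 11597 genes 1462 were higher and 1392 lower with DHT (3 libraries each). KLK3 rose by 4.57 ± 0.24 (edgeR adjusted p = 1.4e-08), FKBP5 by 4.50 ± 0.23, TMPRSS2 by 3.72 ± 0.22, ERG by 2.55 ± 0.24 and KLK2 by 0.98 ± 0.24. STEAP4 (at least 200-fold), PGC (at least 153-fold) and the engulfment gene ELMO1 (at least 62.5-fold) had no fragment in MDV. REG4 (at least 349-fold lower with DHT) and CCN3 (at least 200-fold) had none in DHT, and WNT2 (-6.21 ± 0.72) and the growth factor gene HGF (-5.90 ± 0.33) were lower. Androgen-induced genes were higher for 32 and lower for 2 of 40 (35 and 2 over the list alone, median 1.98), sterol genes higher for 23 of 30 (25 over the list alone, median 1.18), secretory genes higher for 19 and lower for 1 of 23 (21 and 1, median 1.76), and mitosis genes lower for 28 of 30 (30 over the list alone, median -1.89). These 4 lists hold with an estimated correlation. The androgen-repressed list was lower for 8 of 17 (9 lower and 1 higher over the list alone, median -1.46), with an adjusted p of 0.19 with an estimated correlation. INSIG1 (2.36 ± 0.20), SEC24D (3.26 ± 0.47) and TOP2A (-2.74 ± 0.23) are called members. Of 3379 genes at least 2-fold apart in intact poly(A) libraries, 2419 passed the filter on low counts here. Of these 2419, 97.8% had the same direction here and 57.7% were called. The other genes count in neither share.

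In low RIN capture libraries 2029 of 13972 genes were higher and 2532 lower with DHT (3 libraries each). These 4561 calls became 2573 in 1 fit over both protocols (1486 higher and 1087 lower), 2686 with RIN as a covariate and 2970 without the DHT RIN 2 and MDV RIN 3.6 libraries. KLK3 rose by 4.91 ± 0.29 (edgeR adjusted p = 2.0e-06), FKBP5 by 3.74 ± 0.28, TMPRSS2 by 3.69 ± 0.28, ERG by 2.13 ± 0.28 and KLK2 by 0.98 ± 0.30, and ACTB was higher by 1.36 ± 0.25. PGC (7.14 ± 0.63), STEAP4 (6.05 ± 0.41), CCDC141 (5.17 ± 0.41), the keratin KRT14 (5.03 ± 0.33) and the natriuretic receptor gene NPR1 (4.92 ± 0.37) led the rise, and REG4 (-6.78 ± 0.62), CCN3 (-6.70 ± 0.38), SATB1 (-6.02 ± 0.29), SHH (-5.98 ± 0.36) and WNT2 (-5.92 ± 0.29) the fall. Androgen-induced genes were higher for 33 and lower for 3 of 40 (median 1.57), the only list held with an estimated correlation (adjusted p = 0.045). Sterol genes were higher for 25 of 30 (28 over the list alone, median 1.52), secretory genes for 19 of 24 (20 over the list alone, median 1.72) and mitosis genes lower for 29 of 30 (median -1.60), each with an adjusted p of 0.099 with an estimated correlation. Immediate-early genes were lower for 13 and higher for 2 of 25 (14 and 2 over the list alone, median -1.23, adjusted p = 4.4e-03, 0.61 with an estimated correlation), FOS at -3.56 ± 0.29 and EGR3 at -3.45 ± 0.45. The MDV library at RIN 3.3 raises that side of the contrast, with EGR1 at 515 CPM against 149 and 168 in the other MDV libraries. Of 3486 genes at least 2-fold apart in intact capture libraries, 3241 were tested here too. Of these 3241, 99.4% had the same direction and 85.8% were called. In poly(A) only 2419 of 3379 were tested at low RIN, so the shares of the 2 protocols rest on unlike sets. Over all genes tested in both intact and low RIN libraries, folds correlated with r = 0.93 against 0.81 in poly(A). In another measure, the log2 CPM difference between 1 degraded DHT and 1 degraded MDV library was correlated with the intact fold. Its r fell from 0.94 at RIN 9.1 and 9 to 0.86 at RIN 3.5 and 3.6 in capture, and from 0.86 to 0.69 in poly(A). Degraded poly(A) libraries were shallower, and the genes differ (14195 in capture and 13333 in poly(A)). Neither was made equal.

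Did the DHT effect itself depend on RIN? In poly(A) (12 libraries), 143 of 13310 genes had a changed effect, 75 upward and 68 downward, and 2165 had an unadjusted p under 0.05. PATJ (1.73 ± 0.23), DNAJC3 (2.71 ± 0.54) and the repressor SKIL (1.79 ± 0.33) moved up, and NSMCE3 (-2.18 ± 0.19), the ribosomal gene RPS25 (-1.85 ± 0.38), E2F1 (-1.26 ± 0.18) and BMP7 (-1.34 ± 0.25) down. None of the 7 genes given in every comparison was called, KLK3 at -0.63 ± 0.19 (edgeR adjusted p = 0.12). The count rests on single libraries, at 14 to 18 without any one intact library and, without a low RIN one, at 684 (MDV RIN 3.6), 378 (DHT RIN 2.4), 320 (DHT RIN 3.5), 257 (MDV RIN 3) and 245 (MDV RIN 3.3). DESeq2 called 843. In capture (12 libraries) 1 of 14662 genes was called, LRAT, a retinol acyltransferase gene (-2.26 ± 0.25, adjusted p = 8.0e-03, 4:155665434-155670355), and 950 had an unadjusted p under 0.05. DESeq2 called 74 there, and 31 were called with no filter. Without 1 library the count was 1091 (DHT RIN 2.4), 33 (MDV RIN 3.3), 4 (MDV RIN 3.6) or 0 (intact MDV replicates 1 and 2, intact DHT replicate 3). Without DHT RIN 2 and MDV RIN 3.6 together LRAT is not called. KLK3 had -0.13 ± 0.23 (adjusted p = 0.97). No list held with an estimated correlation in either protocol. Immediate-early genes in capture had none called (9 lower over the list alone, median -0.59, 0.50 with an estimated correlation). With a simulated change of 2-fold, 20.9% of 67 genes were recovered in poly(A) and 28.4% of 67 in capture, so changes of that size can be missed.

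**Figure D4:**
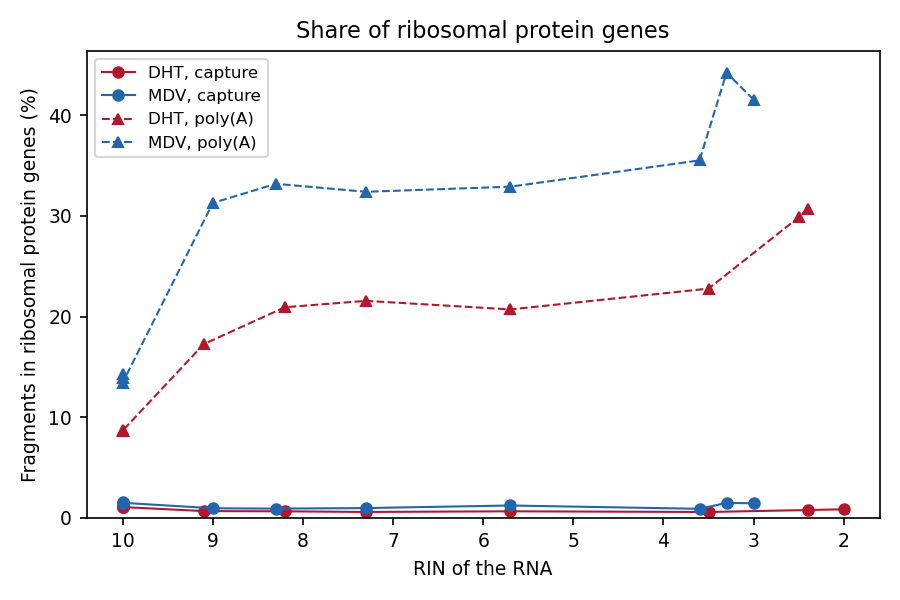
Percent of fragments in ribosomal protein genes of each library, by RIN and protocol.

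Which genes followed RIN over all 20 libraries of a protocol? In poly(A), 1978 of 13190 genes rose and 2687 fell per RIN unit lost. LUC7L3 (0.72 ± 0.03), UPF2 (0.71 ± 0.04), PHF14 (0.71 ± 0.06) and ANKRD18B (0.93 ± 0.14) rose, RNF207 (-0.60 ± 0.08), PRLR (-0.60 ± 0.08) and ZBTB20 (-0.58 ± 0.08) fell, and MALAT1 fell by 0.46 ± 0.14. A fitted slope need not mean an even change. UPF2 in MDV poly(A) was at 61 CPM at RIN 9, against 101 to 109 in intact and 1132 to 1529 in low RIN libraries. In capture, 5054 of 15024 rose and 5642 fell. TCHH (0.71 ± 0.07), MYH3 (0.55 ± 0.02), NEB (0.47 ± 0.04) and ANKRD11 (0.46 ± 0.03) rose, and FPGT (-0.41 ± 0.04), ATP5MC1 (-0.37 ± 0.04) and SC5D (-0.36 ± 0.03) fell. ERG rose by 0.13 ± 0.02 and KLK3 fell by 0.09 ± 0.01 per unit. In poly(A), ribosomal protein genes rose for 64 of 78 (66 over the list alone, median 0.25, adjusted p = 3.1e-45) and very long mRNAs fell for 27 of 38, at 0.11 and 0.20 with an estimated correlation. In capture very long mRNAs rose for 33 and fell for 2 of 39 (median 0.18, adjusted p = 5.2e-15) and sterol genes fell for 22 and rose for 3 of 30, at 0.41 and 0.49 with an estimated correlation. RIN and the title number are confounded. With the number as a factor the 4665 calls in poly(A) became 737 and the 10696 in capture 4990, and with only the numbers that hold RIN 7.3 and lower they became 2044 and 2689.

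**Figure D5:**
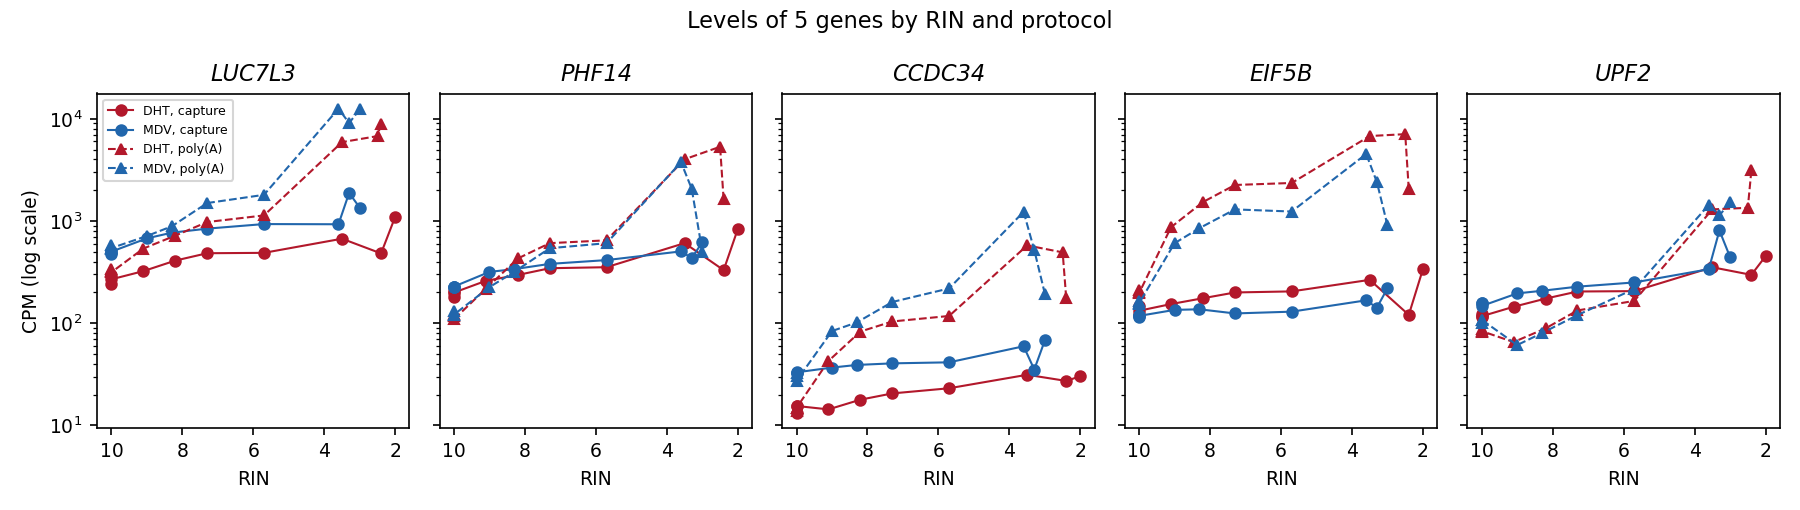
Levels of genes that rose with degradation in poly(A) libraries, by RIN and protocol.

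Genes without overlap between the groups made up 80.5% of those tested for DHT in intact poly(A), 81.0% in intact capture, 40.7% in low RIN poly(A) and 46.1% in low RIN capture, against 10% by chance for 3 libraries against 3. For the contrasts of 6 against 6 the share was 59.4% for protocol in intact RNA, 54.3% for protocol at low RIN, 41.7% for degradation in poly(A) and 55.8% in capture.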

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

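All tests of the pattern at RIN 9.1 and 9 were chosen only after it was seen, and the exchange of labels was fixed before.

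Poly(A) libraries at RIN 9.1 and 9 lay farther from intact RNA than those at RIN 7.3, with differences in similarity of -0.00975 in DHT and -0.0272 in MDV, although they share the title number of the intact libraries. Depth and a few abundant genes are not the cause, since the difference in DHT was -0.0145 after thinning and -0.0102 without the 100 most abundant genes. Loss of sequence far from the tail was predicted to give a steeper fall of the fold with 3' UTR length at RIN 9.1 and 9. It did, with rho -0.559 against -0.414 at RIN 7.3 in DHT and -0.551 against -0.406 in MDV. Removing that trend was predicted to end the order of similarity, which it did not. Over 12402 genes the difference narrowed from -0.0249 to -0.0103 in DHT and, by a smaller share, from -0.0663 to -0.0402 in MDV. Such loss may be a part. Whether it is the whole is not decided, since the trend was removed in bins, from 1 transcript per gene, which can leave a remainder. The weight given to the narrowed difference was chosen after both values were seen. No biological explanation was tested.

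In 48 combinations of a group of 4 libraries and a measure, 4 held a library standing apart. Among replicates about 1 in 20 does so by chance, but each group of 4 is a series of RIN, so that rate need not hold here. The combinations also share libraries and 3 of the 4 are the same library, so they are not independent. In DHT poly(A) at RIN 9.1, KLK3 was at 680 CPM (nearest 363, other end 306), KLK2 at 8138 (5039 and 4867) and ACTB at 842 (554 and 498). That library is the least degraded of its group. Intact DHT poly(A) libraries held 573 to 591 CPM of KLK3, 9583 to 9606 of KLK2 and 789 to 829 of ACTB. KLK2 was at 4191 CPM in MDV poly(A) at RIN 5.7 (2866 and 2669).

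The DHT effect differed between protocols for 366 genes and 9 lists in intact RNA. The lists had medians of -0.26 (androgen-induced), -0.0914 (sterol), -0.17 (secretory), -0.0871 (polyamine), -0.21 (immediate-early), -0.11 (oxidative phosphorylation), 0.20 (ribosomal proteins), 0.36 (nuclear long noncoding, 0.088 without a filter) and -0.53 (histones). More negative in capture was the effect on PMAIP1 (-3.74), RGS2 (-2.74), IER5 (-2.68), SGK1 (-2.62), ARC (-2.5), FOSB (-2.08), TMPRSS2 (-0.62), FKBP5 (-0.56), ERG (-0.43), KLK2 (-0.43) and KLK3 (-0.32), and SCARNA13 (1.28), GAS5 (0.81) and HNRNPA1 (0.68) had the other sign. With labels exchanged, 3 of 100 splits called as many genes and the highest other split called 4043. Exchanging protocol labels unequally in DHT and MDV can turn the large protocol effect into such calls, so these splits do not decide on chance. Where the calls come from was not tested.

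The change with degradation differed between protocols for 9435 genes, and 1 of 100 splits, the real one, called as many (highest other 5613). List medians were -0.87 for polyamine genes and 2.63 for very long mRNAs. More positive in capture were ANKRD11 (4.41), NEB (4.39), MKI67 (4.10), ERG (1.59), FKBP5 (0.90) and TMPRSS2 (0.61), and more negative SREK1IP1 (-5.75), SEC61G (-3.95), RPL22 (-3.74), OAZ2 (-2.30), GAPDH (-1.35) and KLK3 (-0.84).

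The DHT effect differed by RIN for 143 genes in poly(A), where 4 of 100 splits called as many (highest other 1711), and for 1 gene in capture, where 3 did (highest other 3393). Exchanging treatment labels unequally in intact and low RIN libraries can turn the large DHT effect into such calls. These splits therefore do not decide on chance here. The 1 gene in capture is lost on leaving out any 1 of 3 intact libraries, or the DHT RIN 2 and MDV RIN 3.6 libraries together. In poly(A) the named genes are DNAJC3 (2.71), SKIL (1.79), PATJ (1.73), NSMCE3 (-2.18), RPS25 (-1.85), BMP7 (-1.34) and E2F1 (-1.26), and in capture LRAT (-2.26).

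For the remaining counts, splits of 3 against 3 libraries are too few for a share under 0.05 (1 of 10 each), with 10591 and 11388 real calls for DHT in intact poly(A) and capture, 2854 and 4561 at low RIN, and 0 in the highest other split of each. Of 100 splits only the real one called as many for protocol in intact RNA (10817, highest other 6), protocol at low RIN (9696, highest other 0), degradation in poly(A) (7109, highest other 2039) and capture (10652, highest other 4893), and the RIN trend in poly(A) (4665, highest other 3738) and capture (10696, highest other 2316). Exchanging labels among these libraries thus seldom gives such counts, but it does not cover the spread of cultures. For degradation and the RIN trends it also does not separate RIN from the title number.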

How the results depend on the processing

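Alternatives added after the results were seen are those without the DHT RIN 2 and MDV RIN 3.6 capture libraries, without the DHT pair of RIN 2 and 2.5 in the degradation interaction and the similarity, and without RIN 9.1 and 9 in the trends. Of 247 alternative fits, most kept the count of calls within 1.5-fold, and the cause of the changes below was not tested. Leaving out 1 library at a time gave 219 to 778 genes for the DHT effect by protocol, 14 to 684 for the DHT effect by RIN in poly(A) and 0 to 1091 in capture. DESeq2 called 843 and 74 genes for the DHT effect by RIN in poly(A) and capture, and capture without a filter 31. Low RIN against RIN 7.3 and 5.7 called 1486 genes in poly(A) and 2796 in capture, where fewer libraries and a smaller step in RIN are compared. With it TMPRSS2 (0.42) turned positive in poly(A) and was not called. DHT against MDV in low RIN capture called 2573 genes in 1 fit over both protocols, 2686 with RIN as a covariate and 2970 without the DHT RIN 2 and MDV RIN 3.6 libraries. The RIN trend called 737 genes in poly(A) and 4990 in capture with the title number as a factor, and 2044 and 2689 with only the title numbers that hold RIN 7.3 and lower. A replicate block for the RNA called 8927 genes for protocol at low RIN against 9482 without it on the same libraries, and deviations of libraries of the same RNA correlated at -0.0152 to 0.113.

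With an estimated correlation, list calls fell to 5 for DHT in intact poly(A), 4 in intact capture, 4 in low RIN poly(A) and 1 in low RIN capture, 9 for the DHT effect by protocol, 5 for protocol in intact RNA and 0 at low RIN, 3 for degradation in poly(A), 0 in capture and 2 for their difference, and 0 for the DHT effect by RIN and for the RIN trends in both protocols. Without the DHT pair of RIN 2 and 2.5, 7 lists were called for the DHT effect by RIN in capture, and 9 list tests changed direction, none of them called without the pair. These were stromal markers in the degradation interaction (adjusted p = 0.93), luminal (0.94) and very short genes (0.98) for DHT in low RIN poly(A), steroid metabolism (0.67) and nuclear long noncoding RNAs (0.67) in low RIN capture, polyamine genes in the DHT effect by RIN in poly(A) (0.77), androgen-repressed genes in capture (0.38), and basal markers in the poly(A) (0.86) and ribosomal proteins in the capture trend (0.93). Similarity over genes of at least 10 CPM related to RIN with r = -0.349 in DHT and -0.0276 in MDV poly(A), and exceeded poly(A) in capture by 0.0540 in DHT (exact adjusted p = 0.14) and 0.0579 in MDV (exact adjusted p = 0.13).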

Other observations

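Library levels in the next paragraph, the tests of genomic DNA, of A-rich stretches and of transcript length, and the alternatives without certain libraries were chosen only after results were seen.

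FOS, RGS2, EGR1 and ARC, picked from the immediate-early genes after results were seen, were higher in capture than in poly(A) libraries in cells given MDV, and the list was not tested in MDV alone. In intact RNA, FOS was at 16.6 to 18.9 CPM in MDV capture against 1.16 to 2.00 in MDV poly(A), while DHT libraries had 2.69 to 3.20 and 0.351 to 0.584. RGS2 was at 7.53 to 8.00 against 0.852 to 1.38 in MDV and at 0.472 to 0.600 against 0.30 to 0.779 in DHT. EGR1 was at 71.1 to 77.5 CPM in MDV capture against 18.6 to 19.7 in poly(A) (DHT 27.8 to 31.2 and 9.02 to 10.4), and ARC at 11.1 to 12 against 1.48 to 1.64 (DHT 3.16 to 3.36 and 2.16 to 2.80), so FOS, EGR1 and ARC were higher in capture in DHT too. Among low RIN capture libraries of MDV, that at RIN 3.3 stood out with 515 CPM of EGR1 (149 and 168 in the other two), 510 of IER2 (136 and 111), 142 of ARC and 279 of RASD1. No cause was tested.

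MALAT1, a nuclear RNA whose 3' end is a triple helix and not a tail, took 0.217 to 0.367% of intact poly(A) libraries, 0.678 to 1.16% at RIN 9.1 to 7.3, 0.508% (DHT) and 0.0526% (MDV) at RIN 5.7, and 0.0188 to 0.0816% at low RIN, against 0.366 to 3.41% in capture. LUC7L3 rose in small steps and then abruptly in DHT poly(A), from 315 to 342 CPM in intact RNA through 537 at RIN 9.1 and 1133 at RIN 5.7 to 5910 at RIN 3.5 and 8978 at RIN 2.4. In DHT capture it reached 1102 CPM at most from 242 to 295.

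Capture libraries of DHT RIN 2 and MDV RIN 3.6 held fragments of 20308 and 18972 genes, against at most 18160 in the other 18, and depth is excluded, since after thinning the lower of them still had 18470 genes against 17737. Genomic DNA fits the share of olfactory receptor genes, mostly silent here, that had a fragment. It was 74.8% and 41.2% of 330 genes against 2.73 to 12.7% in the others. Over 2436 silent genes fragments followed target length (rho 0.417 and 0.319). That rho was not computed for the other 18, so it does not separate genomic DNA from other sources of sparse reads. By the rate of olfactory fragments per library, however, MDV RIN 3.6 (8.96) lies below MDV RIN 8.3 (12.3) and RIN 9 (15.7), where fewer genes hold them. The shares suggest genomic DNA, less clearly at MDV RIN 3.6, and rare transcription by the cells was not tested apart. Without both libraries, DHT against MDV in low RIN capture called 2970 genes.

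Genes at least 4-fold higher in low RIN poly(A) libraries (343) were examined for A-rich coding stretches, an idea that came from the gene names, with the prediction written before the share was computed. Of 277 with a coding sequence, 7.94% hold at least 16 A in 20 bases, against a median of 1.44% and at most 3.61% in 1000 matched lists, while 2.88% of 278 genes at least 4-fold lower do. Short transcripts that keep their tail fit too, as 82.5% were shorter than the median of 3058 bases, and genes with the fewest A (under 8) were also often 4-fold higher (11.8% of 195). The shares of 7.94% and 82.5% fit selection on what stays joined to an A stretch, internal or terminal, in fragmented RNA. A stretches account for few of the genes, and such a stretch did not by itself go with a rise. The 373 genes with at least 16 and under 18 A had a median log2 fold change of -0.44 in poly(A). Of these, 5.09% were at least 4-fold higher. The 12 genes with 18 A or more had a median of 0.67, and 25% were at least 4-fold higher. Genes under 8 A had a median of 0.73. In capture the 343 genes at least 4-fold higher in poly(A) had a median of -0.05, with 106 higher and 93 lower of 311 tested. As a set these genes thus did not rise in capture. Single ones did, as LUC7L3 in MDV capture, at 929 to 1880 CPM in low RIN against 474 to 510 in intact libraries. RNA was degraded in lysate, after the cells were broken, and a change in the cells themselves was not tested.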
